A study of Caenorhabditis elegans with 3 samples.

How the data were processed

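PQM-1, a zinc finger transcription factor of the nematode Caenorhabditis elegans, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L4 larvae of mixed sex. The worms carried a transgene that encodes PQM-1 with GFP and FLAG at its C-terminus, in an unc-119 mutant strain (OP201). The 3 libraries form 1 group and come from 2 biological replicates, with 2 technical libraries in replicate 1 and 1 library in replicate 2. With 1 group there was no comparison between conditions, and the tests below compare sites, genes and windows of the genome within the group. Each replicate came from its own biosample, per the labels.

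Starting material was 8 peak lists deposited by the authors, 4 on genome build ce11 and the corresponding 4 on ce10. Per the readmes deposited with them, these are the peaks of replicate 1 (its libraries in 1 alignment), those of replicate 2, those of both replicates pooled, and an optimal list thresholded by the irreproducible discovery rate (IDR). The first 3 kinds were made as input for the IDR step and also hold background peaks. Each list gives per peak a signal value set by the authors against a control alignment, and the deposited −log10 q value, which is capped within each list and was constant at 4.04 in the optimal list. Because of that cap, peaks were ranked by signal, and signal was used to describe, rank, filter and test peaks within a list. Levels were not compared between lists, apart from the correlation between replicates, the maximum on each build and the end of the optimal list within the pooled list. The peak caller, the aligner, the IDR version and its threshold are not given in the sources used here, and the control library named in the labels was not used here. Lists of peaks hold no read counts, so the depth of each library is unknown here and no interval below covers read depth. Peaks on ce11 lay within the chromosome lengths of the WBcel235 assembly, the same build, whose sequence and Ensembl annotation release 115 were used for genes and motifs. The ce10 lists served for counts and signal values only, and no coordinate was converted between builds.

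The tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined, apart from the alternatives and tests said to be chosen later. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of the outermost start of a protein-coding gene, and a gene had a promoter peak when at least 1 summit lay there. Summits outside promoters were assigned, in this order, to 5' UTR, 3' UTR, coding exon, intron, other gene and intergenic sequence. Shares carry exact Clopper-Pearson intervals at 95%. The locations and gene biotypes were tested against 10000 circular shifts of all summits within each chromosome (two-sided permutation test, smallest p = 0.0002). Densities were compared by a two-sided permutation test over 1 Mb bins with 100000 resamples (smallest p = 2e-05). Chromosome centres were bins with midpoints in the middle 50% of an autosome. Motif windows of 201 bp around summits were compared with windows of the same size 1000 bp to each side that overlapped no optimal peak, by two-sided Fisher's exact tests. Words of 7 bases, reverse complements merged, were tested in the same windows. Gene lists and gene-name classes with at least 10 members were compared with all other nuclear protein-coding genes by two-sided Fisher's exact tests. Their odds ratios were formed after a small constant was added to each cell, which moves them off the ratio of raw counts, most in short lists. Folds of gene lists over shifts are the count over the mean shifted count, with the same constant added to both. Tests over locations, motifs, words, gene lists, gene-name classes, gene biotypes and signal were adjusted within each family by the Benjamini-Hochberg method. Densities, correlations and other single comparisons were not adjusted. Fisher's exact p-values of motifs and words below 1e-300 were set to 1e-300. Neighbouring genes in opposite orientation can share a peak, and downstream genes of an operon may have no promoter of their own.

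Replicates were compared by the share of optimal peaks overlapped by at least 1 bp in each replicate's list and by the correlation of signal across peaks (100000 permutations, smallest p = 1e-05). Peaks are not independent replicates, so these p-values describe peaks and not animals. Of each replicate's list, as many of its strongest peaks as there were optimal peaks gave the values without the other replicate. Named genes are those at the 25 strongest peaks, with the nearest gene start where the peak lay in no promoter. Also named are up to 4 members, by signal, of each gene list that passed the test and of the insulin, tissue and yolk lists, up to 3 of each class found by the scan, and pqm-1, unc-119, daf-16 and elt-2 in any case. Alternatives covered the peak threshold, each replicate left out, the peak midpoint, promoter size, gene start, background, bin and window size, and the overlap rule. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The promoter share, gene list, promoter peak, motif, X density and correlation statistics were tested on simulated data, and the others were not: a density set 1.5 times higher on X was recovered as 1.44 times, and of 1000 random lists of 40 genes 2.1% passed 0.05. In these random lists each gene's peak was drawn independently, whereas neighbouring genes in the data can share a peak. The 2.1% therefore does not cover lists whose members lie close together.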

Results

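PQM-1 occupancy was measured by ChIP-seq in L4 larvae, from 3 libraries of 2 biological replicates in 1 group, and the optimal list held 4739 peaks on ce11. Their median width was 344 bp, a width shared by 82.0% of them, and together they covered 1470 kb, or 1.47% of the nuclear genome. The authors' signal ran from 31.5 to 350 with a median of 55.4. The lists of replicate 1, replicate 2 and both pooled held 24037, 19038 and 18821 peaks, background included. All 4739 optimal peaks were the 4739 peaks of highest signal in the pooled list, the weakest of them at 31.4968 and the strongest pooled peak left out at 31.495. Read depth is unknown from these lists.

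The strongest PQM-1 peak, with a signal of 350, lay on chromosome IV at 3899846 to 3900173 (ce11) in the promoter of srz-62, a chemoreceptor-family gene, with its summit at −476 bp from the start, upstream being negative. Next came an intergenic peak on chromosome IV at 13919271 to 13919534 with a signal of 339, whose offset from the nearest start, that of Y37A1A.2, was −6381 bp, and a peak of signal 337 in the promoter of T24E12.13 on chromosome II at 3786599 to 3786879. Promoter peaks among the 25 strongest also stood at F16G10.6, sem-5 (an adaptor protein of receptor tyrosine kinase signalling), fbxc-29, B0507.3, ZK550.2, K06G5.1, haf-9 (an ABC transporter of gut granules), rpl-3 (a protein of the large ribosomal subunit) and scav-6. The peak upstream of sem-5 had a signal of 266 and that of haf-9 a signal of 220. Intronic sites included peaks in vhp-1, a MAP kinase phosphatase gene, at 228 and in egl-44, which encodes a TEAD-family transcription factor, at 214.

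These 25 sites had signals from 207 to 350, and 11 of them lay in promoters. TGATAAG occurred in 17 of their windows and the GATA core WGATAR in 24, the exception being the peak of rpl-3 with a signal of 213. Every site of the 25 was overlapped in both replicates, for example with a signal of 110 in replicate 1 and 237 in replicate 2 at srz-62. Outside promoters and the introns already named, the nearest starts were those of zig-13, T13B5.9, R12C12.9, laat-1 (a lysosomal amino acid transporter), C08E8.3, hyl-1 (a ceramide synthase), mob-2, hmbx-1, ifb-2 (an intestinal intermediate filament protein), lap-1 and Y69E1A.8. Offsets from these starts were smallest at T13B5.9, with an intronic summit at 619 bp, and largest at hyl-1, at −8274 bp. The summit nearest to hyl-1 lay upstream of that gene, in an intron of another gene.

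Almost all optimal PQM-1 sites were found in each replicate's own list. Of the 4739 peaks, 4703 (99.2%, 95% CI 98.9 to 99.5) were overlapped by a peak in both replicates, 36 in 1 replicate and 0 in neither. A high share follows largely from how the lists were made. The optimal peaks were chosen from the same replicates, and each replicate's list also holds background peaks. Signals at these 4703 peaks correlated between replicates with a Spearman rho of 0.582 and a Pearson r of 0.732 (permutation p = 1e-05 for each, the smallest 100000 permutations can give). This correlation is across peaks, which are not independent replicates, and the optimal list was drawn from the pooled signal of the same replicates. Among the weaker 50% of the peaks rho was −0.171 (permutation p = 1e-05, an alternative chosen after seeing the data). These peaks were picked for a pooled signal between 31.5 and 55.4, so a peak low in 1 replicate tends to be high in the other. The permutation takes no account of that selection, so its p-value decides nothing on the replicates' agreement. Of replicate 1's top 500 peaks, 304 (60.8%) met a top 500 peak of replicate 2, and of its top 4739 peaks 3629 (76.6%) met a top 4739 peak, shares that rise with the number taken.

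Promoters were the most frequent location of PQM-1 summits. The promoter share was 47.1% (2234 of 4739, 95% CI 45.7 to 48.6), 2.21 times the 21.4% ± 0.629 (SD over 10000 shifts) of shifted summits. Coding exons held 2.81% of summits, 0.144 times the share of shifted summits, and introns held 22.7%, 0.751 times that share. Upstream positions prevailed, with 64.8% of summits 5' of the nearest protein-coding start and a median offset of −137 bp. For these locations the permutation p was 0.0002, the smallest the shifts can give (adjusted p = 0.0003).

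Among the rarer locations, 5' UTRs held 1.27% of summits (1.52 times the shifted share, permutation p = 0.0026, adjusted p = 0.003). The 3' UTRs held 1.18% (0.453 times) and other genes 1.67% (0.484 times), both with a permutation p of 0.0002 and an adjusted p of 0.0003. Intergenic sequence held 23.2%, 1.05 times the shifted share, a difference that did not pass (permutation p = 0.0834). At the strongest 4739 peaks of each replicate alone the promoter share was 47.1% in replicate 1 and 47.1% in replicate 2. Distal sites remained a minority, with 428 summits (9.03%) more than 5000 bp from any protein-coding start.

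**Figure D1:**
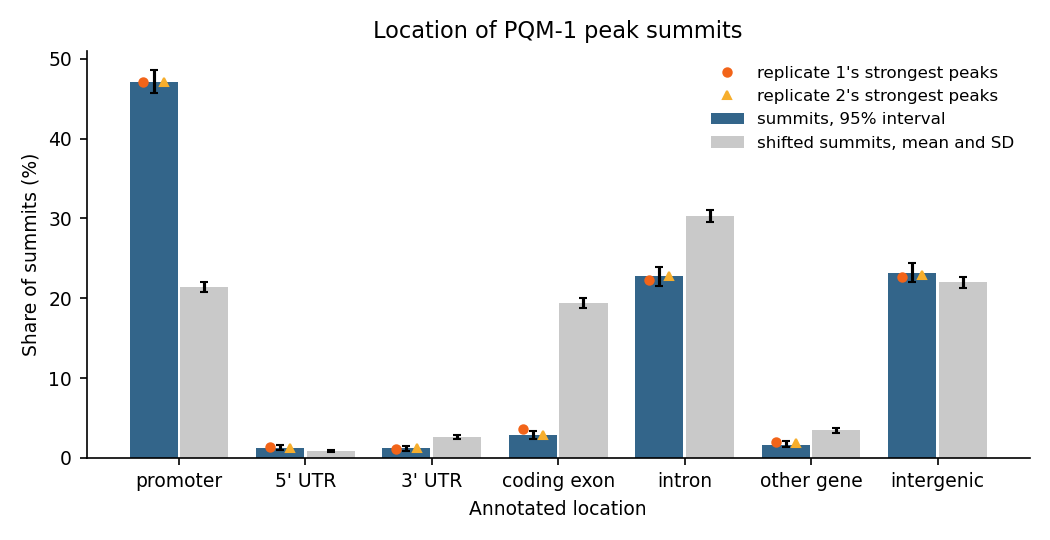
Share of PQM-1 peak summits (%) in each annotated location. Blue bars are the 4739 optimal peaks with 95% intervals, grey bars are shifted summits with mean and SD, and points are the strongest peaks of each replicate. Promoters hold 47.1% of summits against 21.4% of shifted summits, and coding exons 2.81% against 19.5%.

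The X chromosome carried PQM-1 peaks more densely than the autosomes. Bins of 1 Mb on X held 58.9 ± 13.9 summits (SD, 17 bins) and autosomal bins 44.8 ± 15.7 (SD, 80 bins), a ratio of 1.31 (permutation p = 0.00126). Autosome centres were denser than arms, at 55.5 ± 12.7 summits per Mb (SD, 41 bins) against 33.6 ± 9.28 (SD, 39 bins), a ratio of 1.65 (permutation p = 2e-05, the smallest the resamples can give). The mean of 58.9 on X lay near the 55.5 of autosome centres, and X was not tested against centres. All X bins come from 1 chromosome and neighbouring bins may be alike, whereas the permutation treats bins as independent. X held 1053 peaks, or 38.6 per 100 protein-coding genes, while the autosomes ranged from 19.5 on chromosome V to 24.6 on chromosome III. Counted per protein-coding gene start, the ratio of X to autosomes was 1.76 (permutation p = 2e-05) and that of centres to arms 1.30 (permutation p = 8e-05).

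TGATAAG, the DAF-16-associated element tied to PQM-1 in the literature, was the motif most enriched at summits among those fixed in advance. It occurred in 2090 of 4739 summit windows (44.1%, 95% CI 42.7 to 45.5) and in 297 of 8732 flank windows (3.40%, 95% CI 3.03 to 3.80), a 12.97-fold difference. The core site of GATA factors, WGATAR, occurred in 84.2% of summit windows against 37.0% of flanks (2.28-fold). For both motifs Fisher's exact p was at or below 1e-300. Every TGATAAG contains a WGATAR site, so windows with TGATAAG are part of those with WGATAR. GAGAGA was present in 26.4% against 10.9% (2.42-fold, Fisher's exact p = 8.58e-114).

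The DAF-16 binding element GTAAACA occurred in 4.90% of summit windows and 2.59% of flanks (1.89-fold, Fisher's exact p = 6.06e-12). The E-box CACGTG occurred in 6.27% and 3.40% (1.84-fold, Fisher's exact p = 3.78e-14). The heat shock repeat TTCNNGAA was rarer at summits, at 7.43% against 13.7% (0.541-fold, Fisher's exact p = 2.08e-29). For the CRE TGACGTCA the shares of 1.10% and 0.996% did not differ by the test (Fisher's exact p = 0.593, also after adjustment). The other 6 of the 7 motifs passed after adjustment, with adjusted p-values at or below 7.07e-12 by Fisher's exact test. Summit windows had a GC content of 37.5% and flanks 35.6%. Only TGATAAG was also compared with promoters of genes without a peak. For the other motifs a general difference in sequence between summits and flanks was not tested and stays open.

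TGATAAG also lay close to summits. Its median distance from the window centre was 25 bp in the 2090 summit windows and 52 bp in the 297 flank windows that held it (permutation p = 2e-05 for the mean distance, the smallest the resamples can give). Of 8192 words of 7 bases, 1702 were more frequent and 1672 less frequent at summits after adjustment. TGATAAG had the highest fold of the 10 words with the smallest p, and 8 of these 10 contain GATAA on either strand. The others near the top were GATAAGA (37.2% against 3.03%), CTGATAA (36.5% against 3.83%), ACTGATA (29.6% against 3.09%) and TGATAAC (23.6% against 3.36%). None of 100 rearrangements of the bases of TGATAAG reached its share, the highest being GTGATAA at 18.4%. GTGATAA itself contains a WGATAR site, and rearrangements with and without that core were not separated. They therefore do not set TGATAAG against other GATA sites alone.

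**Figure D2:**
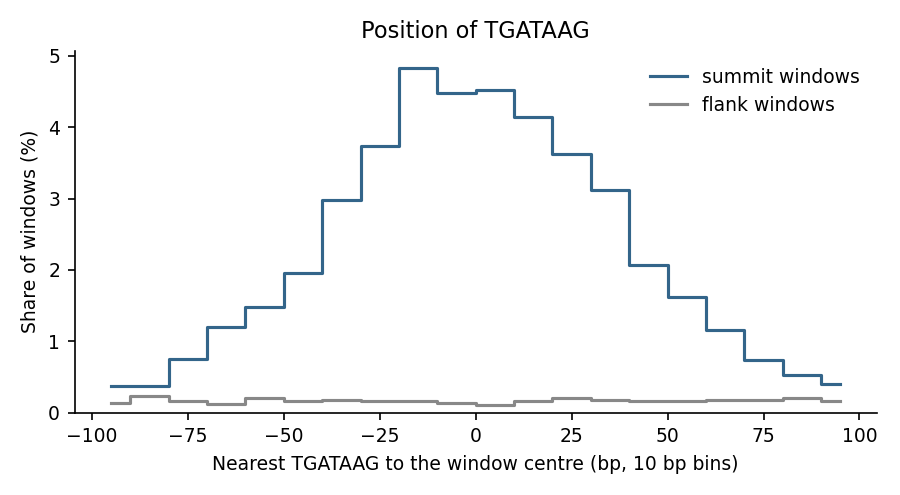
Position of the TGATAAG nearest to the centre of summit windows (blue) and flank windows (grey), as a share of windows (%) in 10 bp bins. Summit windows peak at 4.83% between −20 and −10 bp, and no flank bin exceeds 0.229%.

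Stronger PQM-1 peaks held GATA sites more often, whereas signal at promoter and other peaks did not differ by the test. TGATAAG occurred in 34.5% of the weakest quintile of peaks (95% CI 31.5 to 37.6) and 57.6% of the strongest (95% CI 54.4 to 60.8). WGATAR went from 73.9% (95% CI 71.0 to 76.7) to 95.7% (95% CI 94.2 to 96.9). Peaks with TGATAAG had a median signal of 62.6 and those without 50.5, and mean log2 signal differed by 0.24 (permutation p = 2e-05, the smallest the resamples can give). The promoter share was 47.2% in the weakest and 45.3% in the strongest quintile, and mean log2 signal of promoter and other peaks differed by −0.01 (permutation p = 0.435). TGATAAG was found at 42.7% of promoter peaks and 45.4% of other peaks (Fisher's exact p = 0.0607).

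**Figure D3:**
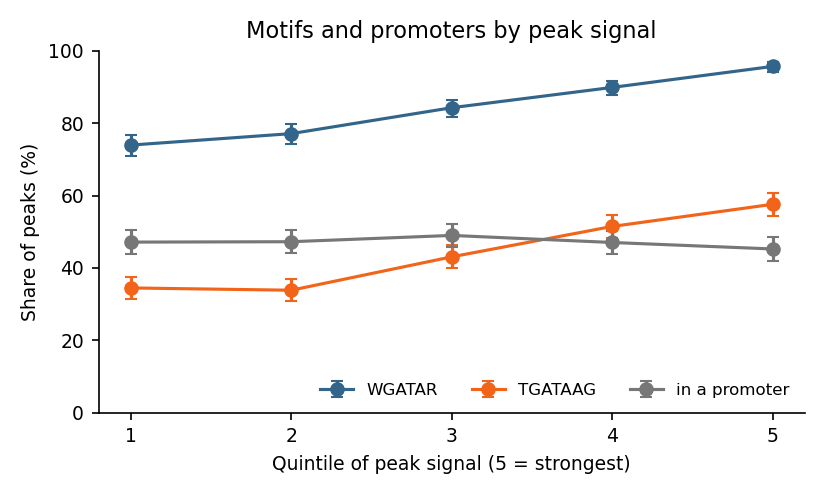
Share of peaks (%) with WGATAR, with TGATAAG and in a promoter, by quintile of the authors' signal (5 is the strongest), with 95% intervals. WGATAR reaches 95.7% and TGATAAG 57.6% in the strongest quintile, where the promoter share is 45.3%.

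PQM-1 summits lay in the promoters of 2553 of 19973 protein-coding genes (12.8%, 95% CI 12.32 to 13.25). Of these, 2463 genes had 1 summit and 90 had 2, among them act-5, an intestinal actin gene chosen after its values were seen, with a strongest promoter peak of 110. A promoter shared by neighbouring genes was common, with 395 peaks (8.34%) in the promoters of at least 2 genes. The count depends on the peak threshold: the stronger 50% of the peaks gave 1267 genes, and 2 times as many pooled peaks gave 4769.

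Intestine markers had PQM-1 promoter peaks far more often than other genes. Of 24 intestine markers, 16 had one (66.7%, 95% CI 44.7 to 84.4, against 12.7% of other genes), an odds ratio of 13.3 (Fisher's exact test, adjusted p = 1.04e-08). The strongest stood at pgp-1 (a P-glycoprotein transporter, signal 202), elt-2 (136), pept-1 (the intestinal oligopeptide transporter, 129) and ifb-2 (124). Markers of other tissues had few promoter peaks: 0 of 15 for body wall muscle (95% CI up to 21.8%), 0 of 17 for hypodermis and cuticle (up to 19.5%), 1 of 24 for neurons (egl-21, signal 41.6), 1 of 20 for the germline (cgh-1, 121) and 1 of 7 for the pharynx (pha-4, 61.8). None of these 5 lists differed from other genes by Fisher's exact test, with adjusted p-values from 0.274 to 1.

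Genes reported to fall when insulin signalling is low (class II) had promoter peaks at 10 of 15 members (66.7%, 95% CI 38.4 to 88.2), an odds ratio of 13.1 (Fisher's exact test, adjusted p = 8.52e-06). They were led by pept-1 (129), dod-23 (93.1), dod-19 (85.4) and nuc-1 (79.5). Genes reported to rise under the same condition (class I) had peaks at 3 of 13 members, an odds ratio of 2.28 that did not pass (Fisher's exact test, adjusted p = 0.380). The 3 were ftn-1 (a ferritin gene, 54.2), mtl-1 (a metallothionein gene, 33.8) and nnt-1 (32.3). In the insulin signalling list 3 of 17 members had a peak, namely ins-7 (66.1), sgk-1 (60.5) and pptr-1 (54.2) (Fisher's exact test, adjusted p = 0.643). None of the 6 yolk protein genes had a promoter peak (95% CI up to 45.9%, Fisher's exact test, adjusted p = 1). Class II and yolk share vit-2 and vit-5, and class II and intestine markers share pept-1 and ges-1. Among other shared genes with a peak, ins-7 is in class II and insulin signalling, and ftn-1 in class I and intestine markers. The lists given below share members too, with dod-22 in class II and innate immunity and vha-6 in intestine markers and vacuolar ATPase. A shared gene counts in each of its lists, so the lists are not fully separate results. Whether class I and class II differ from each other was not tested.

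Genes of endoplasmic reticulum folding, the vacuolar ATPase, innate immunity and lipid metabolism also had promoter peaks more often than other genes. Of 14 genes for endoplasmic reticulum stress and folding, 9 had a promoter peak (odds ratio 11.8, Fisher's exact test, adjusted p = 3.81e-05), led by xbp-1 (a transcription factor of the unfolded protein response, 136), enpl-1 (66.6), pdi-6 (57.6) and pdi-3 (55.0). Without replicate 1 it was 7 of the 14 genes (odds ratio 6.89) and without replicate 2 it was 12 (odds ratio 34.5), both still past the test, and in the stronger 50% of the peaks it was 3 (odds ratio 4.50), which did not pass (Fisher's exact test, adjusted p = 0.132). Vacuolar ATPase genes had peaks at 12 of 20 (odds ratio 10.1, Fisher's exact test, adjusted p = 4.61e-06), with vha-6 at 117, vha-8 at 108, vha-13 at 86.5 and vha-14 at 81.2. Innate immunity genes had peaks at 10 of 20 (odds ratio 6.85, Fisher's exact test, adjusted p = 0.000181), with lys-8 (a lysozyme gene) at 179, irg-4 at 120, lys-1 at 113 and lys-2 at 100.9. Lipid metabolism genes had peaks at 9 of 23 (odds ratio 4.48, Fisher's exact test, adjusted p = 0.00362), with dgat-2 at 152, nhr-80 at 81.7, sbp-1 (the SREBP homologue) at 80.7 and elo-6 at 68.5. The peak of dgat-2 is shared with fbxa-108, whose start is nearer (summit at −72 bp against −846 bp for dgat-2).

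Ribosomal protein genes and 5 other families followed. Cytosolic ribosomal protein genes had peaks at 37 of 81 (45.7%, odds ratio 5.82, Fisher's exact test, adjusted p = 5.59e-12), with rpl-3 at 213, rpl-20 at 125, rpl-15 at 119.4 and rpl-35 at 100.1, none of these 4 with TGATAAG. In the stronger 50% of the peaks it was 12 of 81 (odds ratio 2.67, Fisher's exact test, adjusted p = 0.0174). UDP-glucuronosyltransferases, which conjugate lipophilic compounds, had peaks at 30 of 67 (odds ratio 5.60, Fisher's exact test, adjusted p = 1.17e-09), led by ugt-62 (176), ugt-46 (131), ugt-23 (103.9) and ugt-19 (100.1). Cytochrome P450 genes had 26 of 74 (odds ratio 3.76, Fisher's exact test, adjusted p = 4.46e-06), led by cyp-13A8 (112), cyp-33E2 (107), cyp-37B1 (105) and cyp-25A2 (98.0). Glutathione S-transferases had 13 of 44 (odds ratio 2.93, Fisher's exact test, adjusted p = 0.00597), led by gst-13 (114.7), gst-42 (106), gst-22 (87.9) and gst-38 (75.3). Nuclear hormone receptor genes had 59 of 269 (odds ratio 1.95, Fisher's exact test, adjusted p = 9.2e-05), led by nhr-291 (159), nhr-31 (151), nhr-8 (145) and nhr-35 (111). C-type lectin genes had 47 of 240 (odds ratio 1.69, Fisher's exact test, adjusted p = 0.00597), led by clec-78 (183), clec-265 (168), clec-72 (164.9) and clec-170 (159).

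Chemoreceptor and collagen genes had fewer promoter peaks than other genes. Chemoreceptors had 25 of 1276 (1.96%, 95% CI 1.27 to 2.88), an odds ratio of 0.130 (Fisher's exact test, adjusted p = 3.61e-45), although the strongest peak of all stood at srz-62. The next members by signal were srh-282 (172.1), srh-70 (121) and srz-56 (106). Cuticle collagens had 4 of 156 (2.56%), an odds ratio of 0.200 (Fisher's exact test, adjusted p = 3.81e-05), at col-63 (77.6), col-151 (69.3), col-149 (68.7) and col-69 (42.3). Of the 32 lists tested, 12 were higher and 2 lower, and the other 18 did not pass.

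The remaining lists that did not pass were major sperm proteins (0 of 31, adjusted p = 0.0584), histones (4 of 72, adjusted p = 0.150), translation factors (7 of 31, adjusted p = 0.200) and hypoxia response (2 of 8, adjusted p = 0.415), all by Fisher's exact test. The same held for oxidative stress (3 of 18, adjusted p = 0.643), proteasome (5 of 33, adjusted p = 0.744) and, with an adjusted p of 1 by Fisher's exact test, homeobox genes (7 of 63), aminoacyl-tRNA synthetases (4 of 32), heat shock (2 of 17) and mitochondrial stress and folding (1 of 8). Without replicate 2, mitochondrial stress and folding passed with 4 of 8 genes (odds ratio 6.87) and translation factors with 9 of 31 (odds ratio 2.91), each with an adjusted p of 0.0268 by Fisher's exact test. Collagens lost the call against circular shifts (0.507 times the shifted share, adjusted permutation p = 0.241) and in the stronger 50% of the peaks (odds ratio 0.335), as did P450 (2.41), endoplasmic reticulum (4.50) and glutathione S-transferase genes (2.50) in the latter (Fisher's exact test, adjusted p = 0.0563, 0.0689, 0.132 and 0.132). Glutathione S-transferases also lost it without replicate 2 (odds ratio 2.09, Fisher's exact test, adjusted p = 0.122), and C-type lectins with promoters from 2000 bp upstream to 500 bp downstream (odds ratio 1.31, Fisher's exact test, adjusted p = 0.179). Shifted summits do not favour promoters, so the value of the collagens against shifts is not a comparison with other genes.

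**Figure D4:**
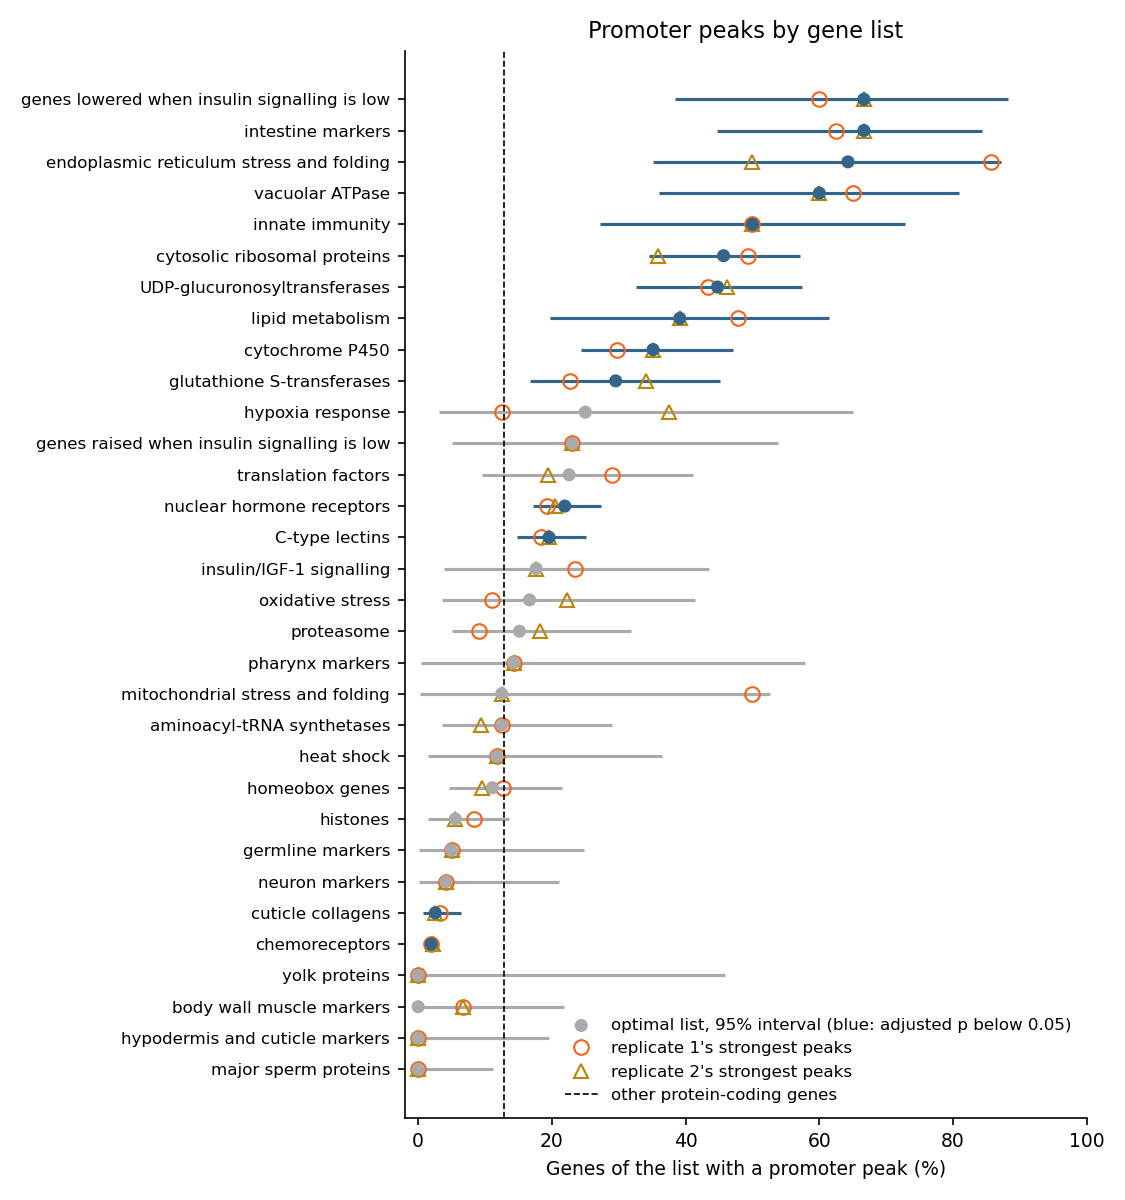
Share of the genes of each list with a PQM-1 promoter peak (%), for the optimal list (filled points with 95% intervals, blue where the adjusted p passed) and the strongest peaks of each replicate (open symbols). Class II examples and intestine markers both reach 66.7%, chemoreceptors 1.96%, and the dashed line marks other protein-coding genes.

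Among 175 gene-name classes, 21 had promoter peaks more often than other genes and 14 less often. Besides the lists above, the classes with the smallest p included fbxa, a family of F-box proteins, with 52 of 170 genes (odds ratio 3.06, Fisher's exact test, adjusted p = 7.55e-08). Its strongest members were fbxa-134 (189), fbxa-108 (152, the same peak as that of dgat-2) and fbxa-54 (142). Short-chain dehydrogenases (dhs) had 14 of 30 (odds ratio 6.02, Fisher's exact test, adjusted p = 0.000114), led by dhs-3 (100.2), dhs-14 (67.8) and dhs-21 (67.7). Aspartyl proteases (asp) had 10 of 17 (odds ratio 9.58, Fisher's exact test, adjusted p = 0.000165), led by asp-2 (133), asp-9 (74.8) and asp-5 (74.2). The dod class, named for genes downstream of daf-16, had 7 of 10 (odds ratio 14.7, Fisher's exact test, adjusted p = 0.000583), led by dod-23, dod-19 and dod-22 (50.9). These 7 genes are also 7 of the 10 class II genes with a peak, so the class repeats that list and is not a separate result.

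Small-subunit ribosomal genes (rps) had peaks at 18 of 31 and large-subunit genes (rpl) at 19 of 47 (Fisher's exact test, adjusted p = 1.8e-07 and 4.85e-05), the rps class being led by rps-1 (79.1), rps-12 (76.9) and rps-20 (66.5). The other 4 of the first 10 higher classes were ugt, cyp, vha and nhr, whose values stand with their lists. The lower classes with the smallest p were mostly chemoreceptors, namely str (3 of 193), srh (8 of 220), srw (3 of 109), srx (0.990% of its genes), srbc (0 of 71), srd (0 of 67) and srt (0 of 61). The collagens, fbxb (1.92% of its genes) and lgc, a class of ligand-gated ion channels (0 of 56), completed the first 10. Adjusted p-values of these 10 ran from 1.12e-06 to 0.00685 by Fisher's exact test.

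Genes for small nucleolar and small nuclear RNAs lay near PQM-1 summits more often than near shifted summits. A summit within 200 bp was found at 54 of 346 snoRNA genes (15.6%, 95% CI 11.9 to 19.9), 6.41 times the shifted share (adjusted permutation p = 0.0005). The same held for 13 of 129 snRNA genes (4.35 times, adjusted permutation p = 0.0008), 15 of 261 miRNA genes (2.39 times, adjusted permutation p = 0.0157) and 447 of 7764 other ncRNA genes (2.10 times, adjusted permutation p = 0.0005). Genes for piRNAs (118 of 15363, 0.445 times, adjusted permutation p = 0.001) and pseudogenes (66 of 2128, 0.399 times, adjusted permutation p = 0.0005) were near summits less often. For tRNA genes (24 of 612, 1.62 times) the adjusted permutation p was 0.0558, and 0 of 20 rRNA genes had a summit (95% CI up to 16.8%). Shifted summits keep neither the preference for promoters, which was 2.21 times for all summits, nor the higher density of autosome centres. The folds therefore cannot separate these gene types from their position near promoters or on arms, which was not tested.

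The elt-2 gene, which encodes the main GATA factor of the intestine, had PQM-1 peaks upstream, whereas none lay near pqm-1 itself. At elt-2 (X, 10481240 to 10483441, ce11, plus strand) a promoter peak with a signal of 136 and a TGATAAG had its summit at −429 bp. The largest of its 4 peaks within 5000 bp had a signal of 149 and a summit at −2029 bp. At daf-16 (I, 10750498 to 10776703, plus strand), which encodes the FOXO factor of insulin signalling, 7 peaks lay within 5000 bp of the gene, none in the promoter at its outermost start. The largest, with a signal of 99.1, was intronic, 2685 bp downstream of that start. Whether any of these peaks lies at an internal mRNA start of daf-16 was not examined.

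Within 20 kb of pqm-1 (II, 11150391 to 11152595, minus strand) and of unc-119 (III, 10902641 to 10908935, plus strand), the gene mutated in this strain, 0 optimal peaks were found, against a median of 2 per protein-coding gene. That count was shared by 22.9% of genes. Both loci were looked at because the plan of the tests took the strain to carry an unc-119 marker beside the tagged pqm-1. Extra copies of either can add reads. Replicate 1's input list had 0 peaks near pqm-1 and 1 near unc-119, against a median of 10, and 0.606% of genes had as few as pqm-1. Replicate 2's list had 1 and 2, against a median of 8. In the pooled input list both loci had 2 peaks, against a median of 8, with largest signals of 9.71 near pqm-1 and 9.35 near unc-119.

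**Figure D5:**
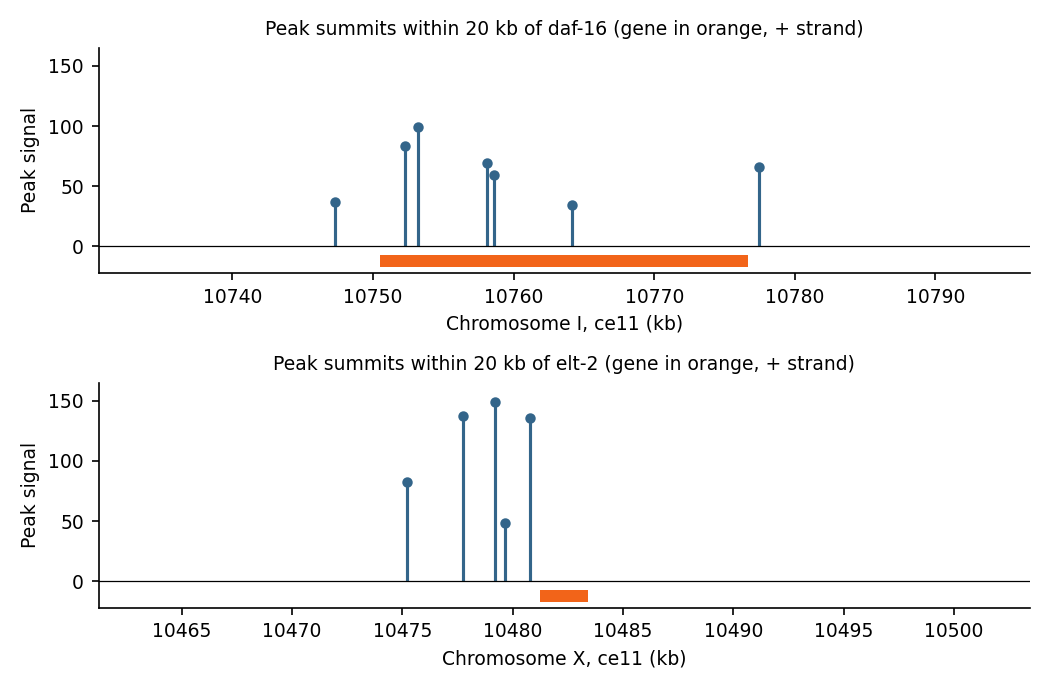
Optimal PQM-1 peak summits within 20 kb of daf-16 and elt-2 on ce11, with position (kb) on the horizontal and the authors' signal on the vertical axis. The genes are orange bars, with 7 peaks around daf-16, the largest at 99.1, and a peak of 149 upstream of elt-2.

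On ce10 the optimal list held 4752 peaks, 13 more than on ce11. The maximum signal was 350 on both builds. X differed most in count, with 1053 peaks on ce11 and 1059 on ce10.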

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

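The mitochondrial peaks were noticed after the lists had been examined, and no test was run on them. Replicate 2's input list held 9 peaks on the mitochondrial genome of 13794 bp, which lies outside the nuclear chromosomes compared above, while replicate 1's list and the pooled list each held 0. Their signals ran from 26.3 to 218 with a median of 88.3, against a median of 10.9 over all peaks of that list.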

How the results depend on the processing

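The correlations in the weaker 50% of the peaks and over all pooled peaks were chosen after the data were seen. The promoter share (36.8 to 61.3%), the ratio of X to autosomes (1.25 to 1.76), that of centres to arms (1.30 to 1.73) and the enrichment of TGATAAG kept their direction and passed their tests under all alternatives run. Against rearranged motifs that enrichment was 19-fold over the median rearrangement, and under the other alternatives it ran from 10.6 to 22.1-fold. Without 1 replicate or the other, the promoter share was 47.1 to 47.1%, the X ratio 1.30 to 1.36, the centre ratio 1.69 to 1.69, the TGATAAG enrichment 11.1 to 12.7-fold, the genes with a promoter peak 2536 to 2539 and the lists past the test 14 to 15. Both settings took as many peaks as the optimal list, so the gene count could move little and does not show that the genes were the same. The number of such genes was 1267 with the stronger 50% of the peaks and 4769 with 2 times as many pooled peaks, which follows from fewer or more peaks. The share of peaks found in both replicates was 86.5% with a reciprocal overlap of 50%, 94.0% with summits within 100 bp and 99.9% in the stronger 50%. Spearman's rho turned to −0.171 in the weaker 50% and was 0.756 over 11120 pooled peaks. The split is made on a signal pooled from both replicates, which by itself pulls rho down within a narrow range. How much of the change this accounts for was not tested. Of 320 odds ratios or folds of gene lists under alternatives, 302 stayed on their side of the test, 7 no longer passed and 11 newly passed. Between 10 and 20 lists passed. Of the 14 lists that passed the main test, 0 reversed direction, and reversals among the lists that had not passed were not counted. The lists that newly passed with 2 times as many pooled peaks were proteasome, translation factors, hypoxia response, mitochondrial stress and folding, histones and major sperm proteins. Translation factors also passed against circular shifts and without replicate 2, and mitochondrial stress and folding without replicate 2. Major sperm proteins also passed with every mRNA start and with the widest promoters. The cause of these changes was not tested. Shifted summits do not favour promoters, so a pass or a loss against shifts does not bear on the comparison with other genes. Homeobox genes, with a peak at 11.1% against 12.8% of other genes, stood at 1.83 times the shifted share. No depth limit can be given because the lists hold no read counts.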

Other observations

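The sites without a GATA core, the GATA counts per window, the motif shares per gene list, the small RNA genes and the distances at yolk genes were chosen after the results were seen. So were all tests of explanations here except those of the nearest gene start and of a wide stretch poor in peaks. Of the 4739 peaks, 750 (15.8%) had no WGATAR in the window, and 59.7% of these lay in promoters (95% CI 56.1 to 63.3) against 44.8% of peaks with the core (Fisher's exact p = 5.30e-14). Their median signal was 44.3 against 58.8, and 22% against 22.3% were on X (Fisher's exact p = 0.924). In these windows the word CTGCGTC occurred in 16.8% against 1.60% of the 5503 flanks that also lacked the core (10.5-fold), AGAGAGA in 21.9% against 3.96% and CACACAC in 15.7% against 2.56%. Windows around all summits held 1.76 ± 1.2 WGATAR sites (SD over windows) against 0.485 ± 0.733 in flanks, and 57.9% held at least 2.

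Promoter peaks of some gene lists differed in GATA content from all other promoter peaks, where WGATAR stood at 79.6 to 80.9%. It was found at 46 of 48 promoter peaks of C-type lectin genes, 1 of 5 of proteasome genes, 4 of 12 of vacuolar ATPase genes, 1 of 9 of endoplasmic reticulum genes and 8 of 35 of ribosomal protein genes (Fisher's exact test, adjusted p = 0.0127, 0.0229, 0.00323, 0.000157 and 5.97e-12). The other 12 of 17 lists did not pass, among them intestine markers with 18 of 18 and class II genes with 12 of 12 (Fisher's exact test, adjusted p = 0.0817 and 0.229). Of the 4737 protein-coding genes with a TGATAAG in the promoter, 1359 had a promoter peak (28.7%), against 7.84% of the 15236 without it. Near miRNA genes the largest signals stood at mir-60 (187), mir-77 (121) and mir-8207 (108), named after their values were seen, and 13 of 15 miRNA peaks had WGATAR against 21 of 54 snoRNA and 4 of 13 snRNA peaks. The peak near mir-77 is also the promoter peak of srh-70. The yolk genes had their nearest peak between 2080 bp (vit-1, signal 93.6) and 15956 bp (vit-5, signal 35.7) from the start.

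The 37 ribosomal protein genes with a promoter peak shared 35 peaks. Binding through a GATA site as at other promoters is argued against by WGATAR at 22.9% of them and 80.9% of other promoter peaks (Fisher's exact p = 3.51e-13), with TGATAAG at 0 of 35. Signal at any strongly transcribed gene stays open: cuticle collagens, with an odds ratio of 0.200, are genes of the hypodermis, where the amount of tagged PQM-1 is not known here, and transcription was not measured. Neighbours' promoters as the cause of the whole excess are argued against by 24 of 81 genes with a peak, an odds ratio of 3.53, when only the gene with the nearest start counts (Fisher's exact test, adjusted p = 1.39e-05, from 5.82 with every gene). For part of the peaks neighbours stay open, since a ribosomal gene's start was the nearest at 65.7% (95% CI 47.8 to 80.9), between the bounds of 50% and 80% set for that test, and no biological explanation other than a GATA site was tested.

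No optimal peak lay within 20 kb of pqm-1. A wide stretch poor in pooled peaks is argued against by 15 of them between 20 and 60 kb away, where the median gene has 14 and 50.1% of genes have fewer. Pooled peaks include background, and optimal peaks at that distance were not counted, so a stretch poor in optimal peaks stays open. A candidate explanation is that extra copies of the tagged construct add reads alike to the sample and its control: the gap between the neighbouring pooled summits was 43.9 kb, against a median of 11.96 kb, and longer than at 92.8% of genes. This falls short of the 95% set for the test, and the rule written for the test counts such a gap against the explanation. That outcome was set aside after the value was seen, because 1 locus gives no spread around it. Around unc-119 the gap was 35.5 kb, longer than at 88.0% of genes. It lay in a stretch with 8 pooled peaks 20 to 60 kb away, where 14.2% of genes have fewer. The explanation by extra copies therefore has no value in its favour that passed its bound, and it stays open. No biological explanation was tested.

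Among the strongest 4739 peaks of each replicate, 1110 of replicate 1 and 1102 of replicate 2 met none of the other's, although 89.1% and 91.0% of these lay in the other's full list. WGATAR stood at 60.8% of the peaks of replicate 1 alone and 78.2% of those of replicate 2 alone (Fisher's exact p = 5.11e-19), and TGATAAG at 23.3% and 37.3% (Fisher's exact p = 8.89e-13). Noise in ranks around the end of each list would give equal shares only if it were equal in both replicates, which is not known, so it stays open. That replicate 1 has more signal away from GATA sites only restates these shares and has no test of its own, so it stays open. Ribosomal protein genes had a promoter peak in replicate 1 alone at 15 and in replicate 2 alone at 4 (exact p = 0.0192, adjusted p = 0.461 over 24 lists), and depth, unknown here, and a biological difference between the worm samples stay open as untested.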
